A study of Mus musculus with 12 samples.

How the data were processed

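RNA sequencing had been run on naive CD4 T cells sorted from the spleen and lymph nodes of C57BL/6 mice. The 12 libraries form 5 groups by genotype and time in culture with anti-CD3/CD28 antibodies, and each library was placed in its group by its title. The set named after Mettl3 holds 3 wild type libraries at 0 h, 3 wild type libraries at 48 h and 2 knockout libraries at 0 h, which carry the numbers 1 and 3. The set named after Nudt21 holds 2 wild type and 2 knockout libraries, all at 0 h. The labels do not say that replicates came from separate animals, so the p-values measure the spread between these libraries. By Xist and Ddx3y the groups of the Mettl3 set hold both sexes and so at least 2 animals each, while the Nudt21 libraries all read as male and their spread may be technical.

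The table used was the deposited one, in which the authors give FPKM per gene for 32285 Ensembl genes. Bowtie and the genome build mm10 are named in the submitters' processing notes, with no version or role. The tool that computed FPKM, the annotation and whether counting used strand were not given in the sources used here. Whole reads could not be recovered from the FPKM values, so the depth of each library is unknown from the table, no count test was run, and no counting interval was given. Sums of FPKM ran from 345621 to 386983 per library, and 10716 to 11720 genes reached 1 FPKM. Every column of the table belonged to 1 of the 12 libraries. Of the 32285 identifiers, 32235 were found in the GENCODE M21 annotation of mm10, from which positions and biotypes were taken. For 5606 genes the value was 0 in every library.

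Genes with at least 1 FPKM in at least 2 of the 12 libraries were kept, which left 12511 genes and put 19774 aside. Values were analysed as log2(FPKM + 1), that is with a pseudocount of 1 FPKM. Fold changes are on that scale and understate the change of low genes. One linear model with the 5 groups was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend), which left 7 residual degrees of freedom and a median prior of 2.64. All groups thus shared an estimate of the spread, because 2 libraries alone give almost none. The 5 comparisons were wild type at 48 h against 0 h, each knockout against its own wild type at 0 h, the difference between the changes in the knockouts, and the wild types of the sets against each other. P-values were adjusted by the Benjamini-Hochberg method over the 12511 genes within a comparison, with a threshold of 0.05. The design, the gene lists, the rule for named genes and most alternative settings were set before the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

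The gene lists numbered 28. They covered m6A writers, erasers and readers, cleavage and polyadenylation factors, mTOR pathway components, genes dependent on mTORC1, several metabolic pathways, ribosomal proteins, ribosome biogenesis, cell cycle, naive, activated, effector and regulatory T cell genes, cytokine signalling, apoptosis, p53 targets, stress responses, interferon-stimulated genes, immediate-early genes, histones, mitochondrial genes, T cell lineage genes and markers of 5 kinds of other cells. Lists overlap, so a gene can count in several. Each list was tested with camera from limma, with a preset correlation of 0.01 between genes and adjustment over the 28 lists. Camera sets a list against the other genes, so its direction can differ from the sign of the list's own median. With a correlation estimated from these libraries, none of the 28 lists passed in any of the 5 comparisons, and that adjusted p is printed beside each call. That correlation, 1 value per list for all comparisons, came from the spread within all groups, including that between the Mettl3 knockout libraries. Cell cycle genes had 0.747 and did not pass with activation, although 54 of 55 rose at a median log2 change of 3.76. Not passing with an estimated correlation thus does not show that a list is unchanged. The rotation test fry, which asks whether a list's genes move on balance 1 way, was the other alternative. Glycolysis has 22 listed symbols and 23 measured genes, because Aldoa has 2 identifiers in the table.

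Genes were named by a rule. It took the 10 higher and 10 lower genes of largest fold change in each main comparison, or 5 and 5 in the last 2 comparisons, from those past the threshold with no overlap between the groups' libraries and a mean of at least 5 FPKM in the higher group. Predicted genes, pseudogenes and antigen receptor segments were left out. The rule also took up to 4 passing members of each list, or 2 by smallest p where none passed, and a set of genes fixed beforehand that included Mettl3, Nudt21 and members of the mTOR and cytokine pathways. The text prints part of the genes the rule took, mostly ones that kept their call when a library was left out, so the named genes are sturdier than the whole. Histones, ribosomal proteins, interferon-inducible GTPases and other near-identical genes share reads, and genes that overlap on opposite strands cannot be told apart without strand, so their single values are uncertain.

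The scripts were tested on simulated data made from the 12511 genes with 200 of them changed, 50 at each of 4 fold sizes. For the comparison of 48 h with 0 h, 48% of genes changed 1.25-fold, 86% changed 1.5-fold, 96% changed 2-fold and 100% changed 4-fold were recovered, with 12 false calls. In the Mettl3 comparison the shares were 26%, 70%, 90% and 98%, with 7 false calls. For the Nudt21 comparison they were 26%, 62%, 92% and 100%, with 13 false calls. The difference between the knockouts gave 10%, 46%, 78% and 92%, with 4 false calls, and the wild types gave 26%, 78%, 96% and 96%, with 3 false calls. The simulated noise was independent between genes, with 1 spread per gene for all 12 libraries, and low genes were not among those changed. Real groups differed in spread, with replicates correlating at 0.9252 in the Mettl3 knockout and at 0.9906 or more in its wild type at 0 h. The shares and false calls thus check the scripts and give no error rate for these data.

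Whether equal replicate numbers pair libraries was checked by correlating deviations from the group means. For the wild types at 0 h and 48 h the 3 correlations of equal numbers were 0.26, 0.23 and 0.32, all above 0.1, so these numbers were taken to pair the libraries, a pairing read from the data and not stated by the labels. The alternatives tried were other pseudocounts (0.1 and 0.5), no filter, a filter at a mean of 5 FPKM, median-ratio, quantile and TPM scaling, other variance settings of limma, each library left out in turn, a replicate block, fits of fewer groups, and a minimum change of 2-fold. After seeing the data a covariate for markers of other cells, a correction for GC content and transcript length, crossed numbers in the Nudt21 set, library weights and list tests without the library Mettl3 knockout 3 were added. Polyadenylation site use and m6A marks cannot be measured from FPKM per gene and were not analysed here.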

Results

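Transcript levels were measured by RNA sequencing in 12 libraries of sorted naive mouse CD4 T cells, given as FPKM per gene. Mettl3 encodes the catalytic subunit of the m6A RNA methyltransferase, and Nudt21 encodes a subunit of the cleavage factor that helps to choose polyadenylation sites. The series title names both processes, T cell homeostasis and mTOR signalling. The groups were wild type cells of the Mettl3 set at 0 h (3 libraries) and after 48 h with anti-CD3/CD28 antibodies (3), Mettl3 knockout cells at 0 h (2), and wild type (2) and Nudt21 knockout cells (2) at 0 h. Replicates correlated at 0.9906 to 0.9937 among wild types of the Mettl3 set at 0 h, 0.9919 to 0.9974 at 48 h, 0.996 in the Nudt21 wild types and 0.9922 in the Nudt21 knockouts, but at 0.9252 between the Mettl3 knockout libraries (Pearson's r over log2 values of genes, which are not independent replicates). The depth of the libraries is unknown from the table.

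Each targeted gene was lowest in its own knockout, without reaching 0. The deleted exons are not given, and FPKM per gene cannot show the loss of an exon, so the remaining level does not measure functional transcript. Mettl3 (ENSMUSG00000022160, mm10 chromosome 14, 52294841 to 52305128, protein coding) stood at 26.7, 28.7 and 25.3 FPKM in the wild type libraries of its set at 0 h and at 5.36 and 6.45 FPKM in knockout libraries 1 and 3. Its log2 fold change was -2.02 (SE 0.08, limma adjusted p = 4.03e-06). At 48 h wild type cells held 15.1, 16.4 and 15.3 FPKM. Nudt21 (ENSMUSG00000031754, chromosome 8, 94015496 to 94037031, protein coding) stood at 18.2 and 16.9 FPKM in its wild type libraries and at 7.57 and 6.69 FPKM in its knockout libraries, a log2 fold change of -1.19 (SE 0.07, limma adjusted p = 3.27e-05). In the Mettl3 set, Nudt21 held 17, 18.1 and 19.2 FPKM in wild type cells at 0 h, 31.1, 31.6 and 32.5 FPKM at 48 h, and 17.8 and 17.2 FPKM in the knockout, where it did not pass the test (log2 fold change -0.05, limma adjusted p = 0.63). Mettl3 in the Nudt21 set held 34.4 and 33.9 FPKM in wild type and 29.1 and 26.1 FPKM in knockout libraries. That log2 fold change of -0.3 passed (limma adjusted p = 0.0351) but was lost when Nudt21 wild type 1 (0.139), Nudt21 wild type 2 (0.128), Nudt21 knockout 2 (0.221) or Mettl3 wild type 1 at 48 h (0.0523) was left out, and with median-ratio (0.125) or quantile scaling (0.0561).

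**Figure D1:**
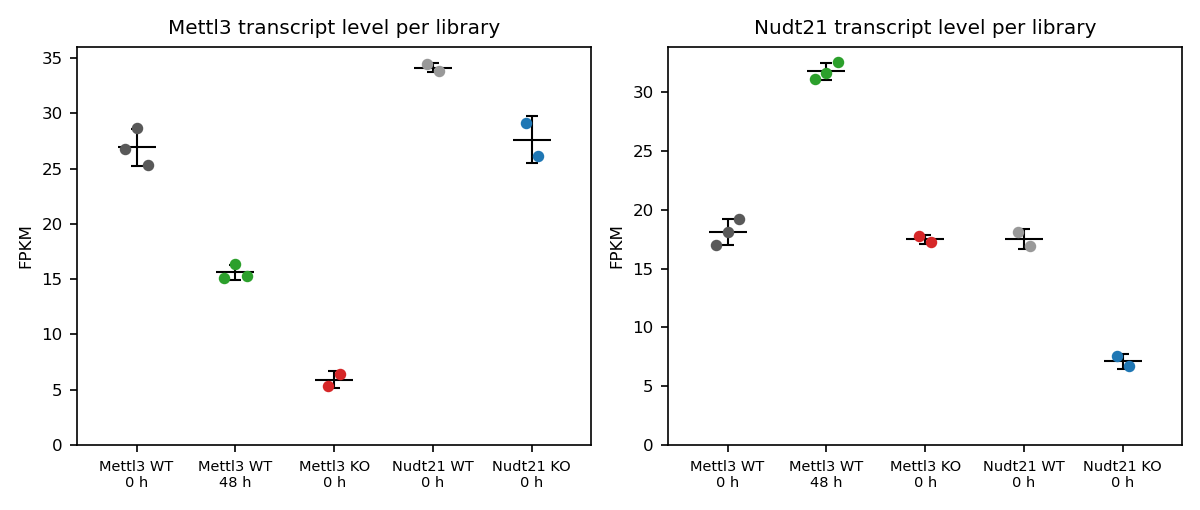
FPKM of Mettl3 (left) and Nudt21 (right) in each of the 12 libraries, by genotype and hours with anti-CD3/CD28. Points are libraries, the wide bar is the group mean and the error bar its SD. Mettl3 averages 5.9 FPKM in its knockout against 26.9 in its wild type, and Nudt21 averages 7.13 against 17.5.

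Activation of wild type cells came first, as the response against which resting knockout cells can be set. After 48 h the cells expressed genes such as Gzmb, Aurkb and Hk2 that resting cells held near 0. Gzmb, which encodes the protease granzyme B (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260), rose from 0.207 ± 0.0592 to 164 ± 60.6 FPKM (mean ± SD, n = 3 and 3, log2 fold change 7.04, SE 0.45, limma adjusted p = 2.42e-07). Il2ra, the high-affinity IL-2 receptor chain, rose from 2.6 ± 0.233 to 184 ± 20.2 FPKM. Tnfrsf9 rose from 4.75 ± 0.441 to 240 ± 16.4 FPKM. In the other direction, the IL-7 receptor gene Il7r (ENSMUSG00000003882, chromosome 15, 9505788 to 9530176) fell from 164 ± 29.8 to 4.58 ± 1.62 FPKM (log2 -4.91, SE 0.22, limma adjusted p = 2.35e-08). The transcription factor gene Klf3 fell from 62.5 ± 3.51 to 5.49 ± 0.507 FPKM. The egress receptor gene S1pr1 fell from 138 ± 15.1 to 21.1 ± 2.49 FPKM. Of 41 T cell activation genes 32 rose, 5 fell and 4 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 9.66e-05, adjusted p = 0.475 with an estimated correlation). Among 29 naive and quiescent T cell genes 26 fell and 1 rose, likewise adjusted over the list alone (camera adjusted p = 7.12e-09, adjusted p = 0.433 with an estimated correlation). T cell lineage genes also fell in 20 of 24 cases and rose in 2, the same adjusted over the list alone, with Cd27 down from 193 ± 7.67 to 60.9 ± 6.87 FPKM (camera adjusted p = 2.18e-05, adjusted p = 0.464 with an estimated correlation). Regulatory T cell genes, a list that shares Il2ra and Tnfrsf9 with activation, rose in 13 of 16 cases and fell in 0, the same adjusted over the list alone (camera adjusted p = 0.00362, adjusted p = 0.565 with an estimated correlation). Effector and memory genes went both ways, with 13 of 32 higher and 7 lower (13 and 6 adjusted over the list alone), Bhlhe40 up from 1.32 ± 0.242 to 137 ± 7.34 FPKM, and no call for the list (camera adjusted p = 0.785).

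Metabolic and proliferation genes rose as groups. Hexokinase gene Hk2 rose from 0.12 ± 0.0124 to 53 ± 3.63 FPKM (log2 5.59, SE 0.27, limma adjusted p = 3.75e-08), and 22 of 23 glycolysis genes rose with it, including Tpi1 at 594 ± 19.3 against 20.2 ± 0.16 FPKM. All 39 measured mTORC1-dependent metabolic genes rose, among them Asns, the asparagine synthetase gene, from 0.118 ± 0.0371 to 41.2 ± 7.65 FPKM. All 32 genes of cholesterol and fatty acid synthesis rose, with Scd2 at 253 ± 8.48 against 19.1 ± 1.77 FPKM. Nuclear-encoded oxidative phosphorylation rose in 49 of 50 genes, for example Ndufb8 from 24.7 ± 0.171 to 86.6 ± 4.76 FPKM. Each of these counts was the same adjusted over the list alone. Camera adjusted p was 6.29e-08 for glycolysis, 8.44e-11 for the mTORC1-dependent genes, 1.2e-08 for cholesterol and fatty acid synthesis and 1.21e-09 for oxidative phosphorylation. With an estimated correlation they were adjusted p = 0.433, 0.433, 0.464 and 0.433. The 13 mitochondrially encoded genes all fell, also adjusted over the list alone, with mt-Nd4 at 443 ± 24.6 against 1100 ± 197 FPKM (camera adjusted p = 0.00178, adjusted p = 0.565 with an estimated correlation). Cell cycle genes rose in 54 of 55 cases, the same adjusted over the list alone, with the mitotic kinase gene Aurkb at 120 ± 1.39 against 0.293 ± 0.0765 FPKM (camera adjusted p = 4.8e-13, adjusted p = 0.475 with an estimated correlation). Of 52 replication-dependent histone genes 43 rose and 4 fell, the same adjusted over the list alone, with Hist1h3c at 35.1 ± 3.02 against 0.151 ± 0.0377 FPKM, although near-identical histone genes share reads (camera adjusted p = 6.29e-08, adjusted p = 0.464 with an estimated correlation). Ribosome biogenesis rose in 40 of 48 genes and fell in 1, the same adjusted over the list alone, with Nop16 at 34.8 ± 2.13 against 11.4 ± 0.533 FPKM (camera adjusted p = 1.38e-05, adjusted p = 0.475 with an estimated correlation). Genes of the ribosomal proteins themselves mostly did not pass, with 14 of 76 higher, 8 lower and 4 and 4 adjusted over the list alone (median log2 0.02, camera adjusted p = 0.767), and Rps27 lower at 257 ± 4.74 against 465 ± 68.8 FPKM.

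Regulators of mTOR signalling split. Eif4ebp1, the gene of a translation repressor that mTORC1 phosphorylates, rose from 1.64 ± 0.393 to 44.2 ± 3.33 FPKM (log2 4.11, SE 0.12, limma adjusted p = 3.77e-09). The mTORC1 inhibitors Tsc1 (log2 -0.38) and Tsc2 (log2 -0.37) fell slightly. Mtor itself held 10.6 ± 0.296 against 10.4 ± 0.252 FPKM and did not pass (log2 0.03, SE 0.06, limma adjusted p = 0.652). With a correction for GC content and transcript length its log2 change was 0.21 and passed (0.0104). Of 60 mTOR pathway components 23 rose and 24 fell, the same adjusted over the list alone, with a median of 0.02, a mean of 0.1 and a camera direction below other genes (camera adjusted p = 0.584). Against no change fry passed the list as lower (fry adjusted p = 0.00567), although its median and mean were positive. Cytokine signalling genes also split, with 16 of 35 higher and 14 lower, the same adjusted over the list alone, a median of -0.02, a mean of 0.26 and a camera direction below other genes (camera adjusted p = 0.836). The STAT5-induced inhibitor gene Cish rose from 8.9 ± 0.484 to 83.6 ± 6.02 FPKM and Socs1 from 17.2 ± 2.5 to 33.3 ± 1.89 FPKM, while Socs3 fell from 64.1 ± 14.5 to 21.7 ± 4.12 FPKM.

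Among m6A writers, erasers and readers 11 of 20 rose and 7 fell (the same adjusted over the list alone, camera adjusted p = 0.904). Mettl3 fell (log2 -0.75, SE 0.07, limma adjusted p = 5.67e-06), and its partner gene Mettl14 rose from 8.57 ± 0.541 to 12.9 ± 0.818 FPKM. Wtap fell from 59.3 to 36.6 FPKM, and the eraser gene Alkbh5 rose from 29.2 ± 4 to 55.5 ± 1.22 FPKM. Cleavage and polyadenylation factors rose in 16 of 25 cases and fell in 6, the same adjusted over the list alone (camera adjusted p = 0.259, fry adjusted p = 8.25e-06 as higher). Nudt21 rose (log2 0.78, SE 0.06, limma adjusted p = 9.4e-07), and Pcf11 fell from 43.1 ± 5.41 to 19.9 ± 1.2 FPKM. Interferon-stimulated genes fell in 33 of 48 cases and rose in 7 (33 and 9 adjusted over the list alone), with Oas2 at 0.216 ± 0.0886 against 20.6 ± 1.44 FPKM (camera adjusted p = 8.59e-06, adjusted p = 0.565 with an estimated correlation). Immediate-early genes fell in 14 of 27 cases and rose in 6, the same adjusted over the list alone, with Fos at 3.32 ± 0.177 against 139 ± 16.5 FPKM (camera adjusted p = 0.011, adjusted p = 0.475 with an estimated correlation). In the integrated stress and unfolded protein response list 22 of 31 genes rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.0388, adjusted p = 0.565 with an estimated correlation). For p53 targets 16 of 26 rose and 7 fell, with Cdkn1a at 46 ± 8.81 against 0.245 ± 0.1 FPKM. For apoptosis regulators 20 of 36 rose and 6 fell, with Bcl2 at 50.8 ± 2.19 against 35.1 ± 3.67 FPKM. Both counts were the same adjusted over the list alone, and neither list passed camera (camera adjusted p = 0.278 and 0.187). Fry passed both as higher (fry adjusted p = 4.02e-06 and 2.88e-06). None of the lists of other cells passed camera, and fry passed only stromal markers, as lower (fry adjusted p = 0.0368). In these, 2 of 22 B cell markers rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.569) and 4 of 20 CD8 T, NK and gamma-delta T cell markers fell (3 alone, 0.187). In the rest, 1 of 28 myeloid markers rose and 2 fell (0 and 1 alone, 0.278), 4 of 10 erythroid and platelet markers fell (1 alone, 0.187) and 1 of 4 stromal markers fell (1 alone, 0.376).

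In limma 9822 of 12511 genes (78.5%) passed between 0 h and 48 h, 5451 higher and 4371 lower, of which 2246 and 1201 changed at least 2-fold. The share of higher genes went from 55.5% to 45.7% with quantile scaling, which also moved the median log2 change of all genes from 0.069 to -0.106, and a correction for GC content and length gave 4225 higher and 5580 lower genes. Of 121 genes that the naming rule took and that passed, 6 lost their call when 1 library was left out, and none of these is named above.

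The Mettl3 knockout was compared with wild type cells at 0 h to ask what resting cells change when the m6A writer gene is targeted. Interferon-stimulated genes had the smallest adjusted p of the 28 lists in camera at its preset correlation. In fry, apoptosis regulators came first (fry adjusted p = 0.000622, against 0.00747 for interferon-stimulated genes). Iigp1, an interferon-inducible GTPase gene (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634), rose from 8.49 ± 5.98 to 91.9 ± 12 FPKM (n = 3 wild type and 2 knockout libraries, log2 3.47, SE 0.56, limma adjusted p = 0.0021). Gvin1 rose from 19.5 ± 9.88 to 165 ± 11.7 FPKM (log2 3.12) and Gbp2 from 24.7 ± 5.59 to 112 ± 28.3 FPKM (log2 2.13). Gbp3 rose from 3.42 ± 1.22 to 20.3 ± 0.416 FPKM (log2 2.3), and Ube2l6, which encodes an enzyme that attaches the ubiquitin-like protein ISG15, from 0.857 ± 0.677 to 21.7 ± 0.247 FPKM (log2 3.67). Gvin1 and Ube2l6 were not members of the list tested. Of 48 interferon-stimulated genes 37 rose and none fell (40 and 0 adjusted over the list alone), at a median of 0.83. The list passed (camera adjusted p = 3.75e-11, adjusted p = 0.727 with an estimated correlation). Its median stood at 0.9 in knockout library 1 and 0.73 in library 3, with 48 and 44 of the 48 members above the wild type mean. Members of the Gbp and related GTPase families share reads, so single values are uncertain.

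Socs1, Cish and Socs3, which encode inhibitors of cytokine signalling, rose alongside. Socs1 (ENSMUSG00000038037, chromosome 16, 10782240 to 10785536), whose product blocks JAK signalling, rose from 17.2 ± 2.5 to 39.4 ± 0.293 FPKM (log2 1.16, SE 0.1, limma adjusted p = 9.76e-05). Cish (ENSMUSG00000032578, chromosome 9, 107296026 to 107302784) rose from 8.9 ± 0.484 to 25.4 ± 2.01 FPKM (log2 1.42, SE 0.11, limma adjusted p = 7.28e-05) and Socs3 from 64.1 ± 14.5 to 157 ± 14.2 FPKM (log2 1.3, SE 0.2, limma adjusted p = 0.00158). The survival gene Bcl2 rose from 35.1 ± 3.67 to 66.7 ± 5.81 FPKM. Il7r held 209 ± 56.2 against 164 ± 29.8 FPKM and did not pass (log2 0.34, SE 0.24, limma adjusted p = 0.305). Of the 35 SOCS family and cytokine signalling genes 15 rose, 5 fell and 15 did not pass, the same adjusted over the list alone (camera adjusted p = 0.028, adjusted p = 0.727 with an estimated correlation, fry adjusted p = 0.00386).

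**Figure D2:**
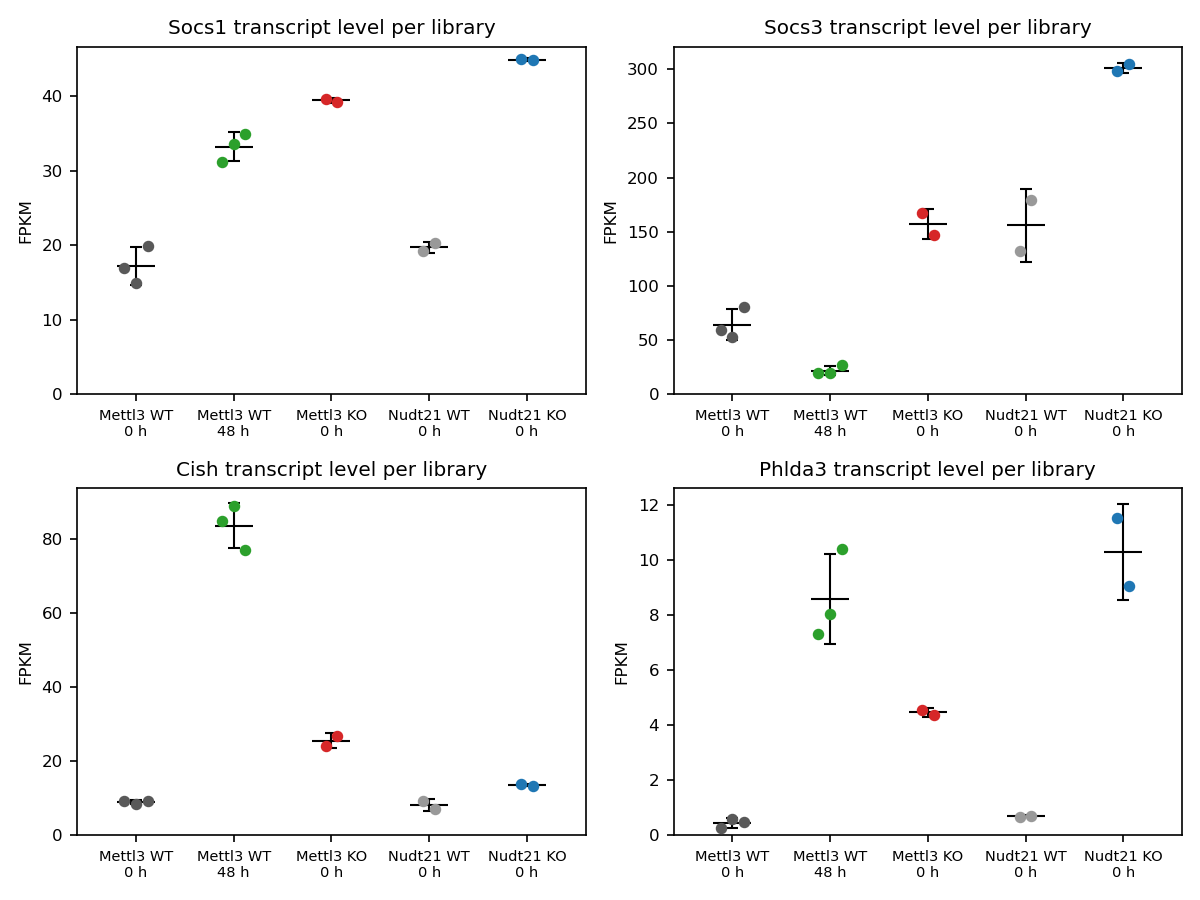
FPKM of Socs1, Socs3, Cish and Phlda3 in each of the 12 libraries. Points are libraries, wide bars group means and error bars SD. Socs1 averages 39.4 FPKM in the Mettl3 knockout and 44.9 in the Nudt21 knockout, against 17.2 and 19.7 in their wild types, while Socs3 also differs between the wild types (64.1 and 156).

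Targets of p53 and regulators of apoptosis rose in part. Cdkn1a, a cell cycle inhibitor gene, stood at 4.72 ± 2.82 against 0.245 ± 0.1 FPKM (log2 2.11, SE 0.26, limma adjusted p = 0.000566) and Phlda3 (ENSMUSG00000041801, chromosome 1, 135766119 to 135769136) at 4.45 ± 0.152 against 0.433 ± 0.168 FPKM (log2 1.93). Pmaip1, which encodes the pro-death protein NOXA, rose to 4.39 ± 2.23 against 0.719 ± 0.135 FPKM (log2 1.59). Among 26 p53 targets 11 rose and 3 fell (14 and 3 adjusted over the list alone, camera adjusted p = 0.0295, adjusted p = 0.727 with an estimated correlation). Among 36 apoptosis regulators 14 rose and 2 fell (16 and 2 adjusted over the list alone, camera adjusted p = 0.00951, adjusted p = 0.322 with an estimated correlation). Apoptosis regulators had a median of 0.12 in knockout library 1 and 0.27 in library 3. Stress response genes rose in 10 of 31 cases and fell in 0 (12 and 1 adjusted over the list alone), among them the chaperone genes Sdf2l1 at 18.5 ± 6.03 against 6.95 ± 0.74 FPKM and Pdia4 at 56.4 ± 7.9 against 34.2 ± 1.43 FPKM (camera adjusted p = 0.00951, adjusted p = 0.727 with an estimated correlation). Without knockout library 3 the median of the integrated stress response and unfolded protein response list went from 0.27 to 0.06 and its call ended (0.0707).

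Components of mTOR signalling changed in both directions. Mtor did not pass (log2 -0.04, SE 0.07, limma adjusted p = 0.677). Tsc2 fell from 19 ± 0.4 to 15.3 ± 0.644 FPKM (log2 -0.29, SE 0.05, limma adjusted p = 0.00203). Castor1, an arginine sensor gene, rose from 10.7 ± 1.77 to 19.2 ± 1.46 FPKM (log2 0.8), and the Rag GTPase gene Rragd from 0.961 ± 0.322 to 4.48 ± 1.92 FPKM (log2 1.45). Eif4ebp1 rose from 1.64 ± 0.393 to 2.92 FPKM (log2 0.57, limma adjusted p = 0.0134), a call lost without knockout library 3 (0.0886), with quantile scaling (0.067) and with library weights (0.0945). Of the 60 components 8 rose, 8 fell and 44 did not pass, the same adjusted over the list alone, with a median of 0.03, a mean of 0.06 and a camera direction below other genes (camera adjusted p = 0.793). Among 39 mTORC1-dependent metabolic genes 7 rose and 5 fell (7 and 6 adjusted over the list alone, camera adjusted p = 0.441). Among 23 glycolysis genes 3 rose and 2 fell (2 and 0 alone, camera adjusted p = 0.438). Cholesterol and fatty acid synthesis fell in 9 of 32 genes and rose in 1 (10 and 1 adjusted over the list alone), including Srebf2, the transcription factor of the pathway, from 79 ± 3.96 to 49.7 ± 3.9 FPKM (log2 -0.66, limma adjusted p = 0.000341), and the enzyme gene Sqle from 9.99 ± 1.94 to 5.26 ± 1.13 FPKM, a call that ended with library weights (0.122). The list passed (camera adjusted p = 0.0267, adjusted p = 0.727 with an estimated correlation), with medians of -0.22 and -0.05 in libraries 1 and 3. Oxidative phosphorylation rose in 10 of 50 genes and fell in 1 (9 and 1 adjusted over the list alone, camera adjusted p = 0.0355, adjusted p = 0.727 with an estimated correlation), with Uqcrfs1 at 80.9 ± 4.06 against 54.1 ± 2.69 FPKM. For the oxidative phosphorylation, nuclear-encoded list the call ended with median-ratio scaling (0.0767), and a correction for GC content and length turned its median from 0.12 to -0.13 (0.0987).

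Genes of RNA processing changed in both directions. Beside Mettl3, the methyltransferase partner gene Wtap rose from 59.3 ± 1.95 to 81.5 ± 3.01 FPKM (log2 0.45, SE 0.05, limma adjusted p = 0.000485) and the m6A reader gene Ythdf2 from 13.8 ± 1.07 to 23.9 ± 3.26 FPKM. In the m6A list 6 of 20 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.158). The polyadenylation factor gene Clp1 rose from 11.1 ± 0.96 to 21.3 ± 1.45 FPKM. Of 25 cleavage and polyadenylation factors 6 rose and 5 fell, the same adjusted over the list alone, with a median of -0.05 and a mean of 0.02 (camera adjusted p = 0.447). Ribosome biogenesis genes rose in 10 of 48 cases and fell in 2, the same adjusted over the list alone, with Ncl, the nucleolin gene, at 96.3 ± 5.61 against 65.4 ± 3.63 FPKM (camera adjusted p = 0.071). The genes of cytosolic ribosomal proteins held a median of 0.02, with 1 of 76 higher and 0 adjusted over the list alone (camera adjusted p = 0.92). Quantile normalization put that median at 0.04 with a call above other genes (0.00592). Histone genes fell in 3 of 52 cases, the same adjusted over the list alone, with a median of 0.07 and a mean of 0.01 (camera adjusted p = 0.727). None of the 13 mitochondrially encoded genes passed in limma, alone or over all genes, yet the list did (median -0.28, camera adjusted p = 0.0306, adjusted p = 0.727 with an estimated correlation). Its median stood at -0.63 in knockout library 1 and 0.08 in library 3, and quantile scaling of the mitochondrially encoded genes ended the call (0.109).

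T cell genes were lower in both knockout libraries. Cd6 fell from 177 ± 20.9 to 94.8 ± 13.9 FPKM (log2 -0.89, SE 0.11, limma adjusted p = 0.000641), and the inhibitory receptor gene Cd5 from 214 ± 27.6 to 131 ± 14.7 FPKM. In the T cell lineage list 14 of 24 fell and 0 rose (16 and 0 adjusted over the list alone), with medians of -0.24 and -0.37 in knockout libraries 1 and 3 (camera adjusted p = 1.51e-07, adjusted p = 0.727 with an estimated correlation). Izumo1r, which encodes folate receptor 4, fell from 70.5 ± 9.1 to 22.5 ± 3.46 FPKM (log2 -1.6) and Rgcc from 52.7 ± 9.62 to 16.1 ± 1.32 FPKM (log2 -1.64). Adh1 (ENSMUSG00000074207, chromosome 3, 138260991 to 138290698) fell from 9.1 ± 1.39 to 2 ± 1.16 FPKM (log2 -1.8). Immediate-early genes fell in 7 of 27 cases, the same adjusted over the list alone, with the antigen-receptor-induced gene Nr4a1 at 84.1 ± 4.51 against 157 ± 33.2 FPKM (camera adjusted p = 0.028, adjusted p = 0.727 with an estimated correlation). For the immediate-early and handling stress genes that call ended with quantile normalization (0.165) and with a correction for GC content and length (0.078). Naive and quiescent genes fell in 9 of 29 cases and rose in 3 (11 and 5 adjusted over the list alone, camera adjusted p = 0.152).

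Knockout library 3 stood apart in effector, proliferation and other-cell genes. Gzmb averaged 20.2 ± 19 against 0.207 ± 0.0592 FPKM (log2 3.77, limma adjusted p = 0.000849), with a log2 change of 2.69 without knockout library 3 and 4.84 without library 1. The chemokine gene Ccl5 averaged 108 ± 118 against 9.03 ± 4.06 FPKM (log2 2.87, limma adjusted p = 0.0108, 1.41 without library 3 and 4.34 without library 1), and the proliferation gene Mki67 7.61 ± 7.56 against 0.924 ± 0.316 FPKM (log2 1.82, limma adjusted p = 0.0155, 0.77 and 2.87). Effector and memory genes rose in 11 of 32 cases and fell in 3 (15 and 3 adjusted over the list alone, camera adjusted p = 0.0238, adjusted p = 0.727 with an estimated correlation), with medians of 0.23 in library 1 and 2.01 in library 3. Without library 3 the effector and memory CD4 T cell genes did not pass (0.512). Cell cycle genes rose in 26 of 55 cases (37, with 1 lower, adjusted over the list alone, camera adjusted p = 6.8e-07, adjusted p = 0.727 with an estimated correlation), with medians of 0.17 and 1.24. T cell activation genes rose in 13 of 41 cases and fell in 4 (15 and 4 alone, camera adjusted p = 0.111), with medians of -0.03 and 0.5. Regulatory T cell genes rose in 6 of 16 cases and fell in 2 (7 and 2 alone, camera adjusted p = 0.0902), with medians of -0.01 and 1.4. B cell markers had medians of -0.15 and 1.79, CD8 T, NK and gamma-delta T cell markers 0.06 and 2.12, and myeloid cell markers -0.14 and 3.54. The medians were also apart for erythroid and platelet markers (-0.51 and 2.78) and stromal markers (-0.17 and 1.7). The light chain gene Igkc read 1238 FPKM in library 3 against 11.5 in library 1 and 13.3, 13 and 31.7 in wild type cells. Passing members were 3 of 22 for B cells (0 adjusted over the list alone, camera adjusted p = 0.028), 6 of 20 for CD8 T, NK and gamma-delta T cells (7 alone, 0.00206), 3 of 28 for myeloid cells (1 alone, 0.00285), 0 of 10 for erythroid cells (0 alone, 0.267) and 0 of 4 for stroma (0 alone, 0.474), all higher. With an estimated correlation they were adjusted p = 0.727, 0.727, 0.727, 0.769 and 0.727. Without library 3 the calls of B cell markers (0.459), CD8 T, NK and gamma-delta T cell markers (0.458) and myeloid cell markers (0.102) ended, and erythroid and platelet markers passed as lower (0.00639).

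**Figure D3:**
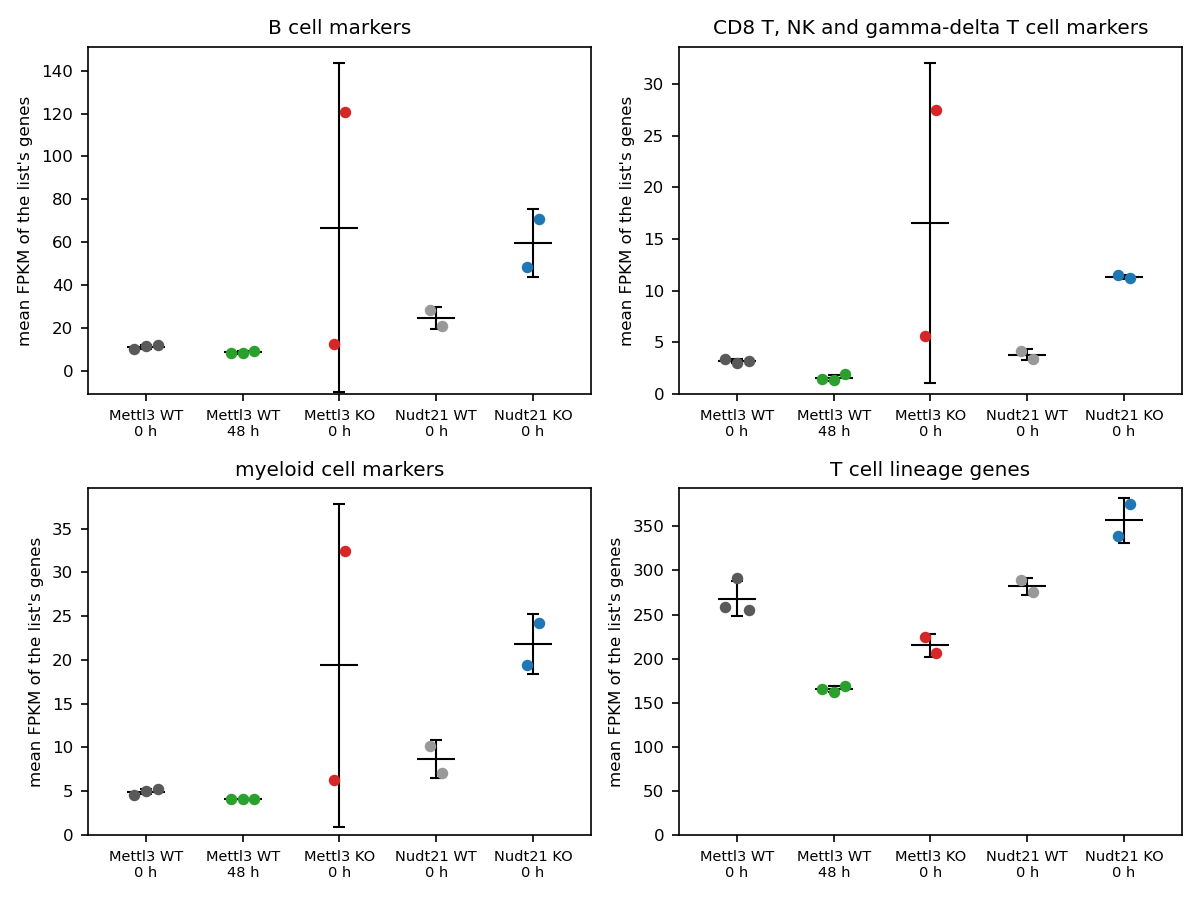
Mean FPKM of the genes of 4 lists in each of the 12 libraries, on linear axes that differ between panels. Points are libraries, wide bars group means and error bars SD. B cell markers read 121 FPKM in Mettl3 knockout library 3 and 12.5 in library 1, and both Nudt21 knockout libraries, at 48.5 and 71, lie above their wild types at 28.3 and 20.9.

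In limma 3610 genes (28.9%) passed between Mettl3 knockout and wild type, 2103 higher and 1507 lower, with 285 and 55 changed at least 2-fold. Quantile scaling gave 1512 higher and 2537 lower genes, moving the median of all genes from 0.043 to -0.062, and a GC content and length correction gave 1388 and 2645, so the balance of directions across all genes depends on scaling. Far fewer genes passed with only the libraries of the 2 groups compared (809) and with library weights (1094). The Mettl3 knockout libraries agreed least of all replicates (0.9252) and had the smallest weights (0.273 each). The spread shared by all groups is thus likely too small for this comparison, and 3610 likely too many. Of the lists above that passed camera, fry did not call cholesterol and fatty acid synthesis (fry adjusted p = 0.298), effector and memory (0.191) or cell cycle genes (0.0679). Immediate-early (0.157) and mitochondrially encoded genes (0.314) did not pass fry either. Neither did B cell (0.242), CD8 T, NK and gamma-delta T cell (0.0848) or myeloid cell markers (0.177). Of 101 passing genes of the naming rule 26 lost their call when 1 library was left out.

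The Nudt21 knockout was compared with its own wild type at 0 h to ask what resting cells change when this cleavage factor gene is targeted. Tmem176b (ENSMUSG00000029810, chromosome 6, 48833818 to 48841496) rose from 2.97 ± 0.549 to 39.6 ± 2.69 FPKM (n = 2 and 2, log2 3.36, SE 0.32, limma adjusted p = 0.000223) together with its neighbour Tmem176a, from 1.76 ± 0.0094 to 22.4 ± 0.709 FPKM. Gp5 rose from 0.164 ± 0.043 to 7.61 ± 0.345 FPKM (log2 2.89), Armh2 from 0.0499 ± 0.00176 to 6.48 ± 0.175 FPKM (log2 2.83) and Drc1 from 2.29 ± 0.28 to 18.7 ± 1.58 FPKM (log2 2.58). Carns1 fell from 20.6 ± 0.983 to 4.77 ± 0.542 FPKM (log2 -1.91), the nuclear long noncoding RNA Neat1 from 29.1 ± 3.56 to 8.72 ± 0.134 FPKM (log2 -1.63) and Adh1 from 9.55 ± 0.519 to 2.32 ± 0.139 FPKM (log2 -1.67).

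Socs1, Cish and some p53 targets rose here too. Socs1 rose from 19.7 ± 0.754 to 44.9 ± 0.168 FPKM (log2 1.15, SE 0.11, limma adjusted p = 0.000213), Cish from 8.1 ± 1.62 to 13.5 ± 0.32 FPKM (log2 0.68, limma adjusted p = 0.00316) and Bcl2 from 24.5 ± 1.36 to 37.3 ± 0.611 FPKM (log2 0.59). Socs3 rose from 156 ± 33.4 to 301 ± 4.78 FPKM (log2 0.96, limma adjusted p = 0.0102), a call lost without wild type 1 (0.0807) or knockout 2 (0.0648). Il7r held 115 ± 5.68 against 162 ± 4.81 FPKM and did not pass (log2 -0.5, SE 0.26, limma adjusted p = 0.186). In the cytokine list 11 of 35 rose and 3 fell (12 and 3 adjusted over the list alone, camera adjusted p = 0.000548, adjusted p = 0.565 with an estimated correlation). Phlda3 rose from 0.683 ± 0.035 to 10.3 ± 1.74 FPKM (log2 2.74, limma adjusted p = 3.27e-05) and Psrc1 from 0.247 ± 0.025 to 6.03 ± 1.03 FPKM (log2 2.49). Of 26 p53 targets 8 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.000506, adjusted p = 0.565 with an estimated correlation). Apoptosis regulators rose in 7 of 36 cases and fell in 2 (2 and 2 alone, camera adjusted p = 0.0689), with the caspase inhibitor gene Xiap down from 10.2 ± 0.378 to 5.81 ± 0.913 FPKM. Stress response genes rose in 2 of 31 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.0987).

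More genes of the mTOR pathway fell than rose, as did genes at large. The leucine transporter gene Slc7a5, of the mTORC1-dependent list, fell from 25.4 ± 1.11 to 14.4 ± 0.411 FPKM (log2 -0.78, SE 0.1, limma adjusted p = 0.000999), and Castor2 from 3.95 ± 0.239 to 2.08 ± 0.203 FPKM (log2 -0.68). Tsc1 fell from 11.9 ± 0.288 to 9.48 ± 0.168 FPKM (log2 -0.3, limma adjusted p = 0.0233), lost without wild type 1 (0.0803), wild type 2 (0.13), knockout 1 (0.0616) or knockout 2 (0.117), and with median-ratio (0.0698) or quantile scaling (0.161). Rps6kb1, the S6 kinase gene, fell from 14.3 ± 0.0434 to 11.6 ± 0.475 FPKM (log2 -0.28, limma adjusted p = 0.0175), lost without wild type 1 (0.0845), wild type 2 (0.0867) or knockout 2 (0.114), and with median-ratio (0.0687) or quantile scaling (0.13). Mtor did not pass (log2 -0.06, SE 0.08, limma adjusted p = 0.612). Of 60 mTOR pathway components 14 fell and 5 rose, the same adjusted over the list alone, while of all 12511 genes 2383 fell and 1092 rose. Against other genes the list did not pass (camera adjusted p = 0.776, adjusted p = 0.78 with an estimated correlation), and against no change it passed as lower (fry adjusted p = 0.00759). Its median of -0.08 stood near that of all genes (-0.051), whose balance of directions depends on scaling. The call in fry thus does not set the pathway apart from other genes. Among 39 mTORC1-dependent metabolic genes 7 fell and 3 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.612). Among 23 glycolysis genes 4 fell and 1 rose (4 and 0 alone, median 0, camera adjusted p = 0.776). Cholesterol and fatty acid synthesis fell in 16 of 32 genes and rose in 1 (18 and 1 adjusted over the list alone), with Sqle at 3.11 ± 0.562 against 8.06 ± 2.05 FPKM (camera adjusted p = 0.000652, adjusted p = 0.639 with an estimated correlation).

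Ribosomal protein genes rose while ribosome biogenesis genes fell. Of 76 genes of cytosolic ribosomal proteins 41 rose and none fell (52 and 0 adjusted over the list alone), at a median of 0.33, which was 0.05 with quantile normalization and 0.43 with median-ratio scaling (camera adjusted p = 4.69e-17, adjusted p = 0.565 with an estimated correlation). Of 48 ribosome biogenesis genes 20 fell and 1 rose (21 and 1 adjusted over the list alone), with Polr1b, a subunit gene of RNA polymerase I, at 14.1 ± 0.276 against 22.7 ± 0.29 FPKM and Utp20 at 6 ± 0.96 against 10.5 ± 0.259 FPKM (camera adjusted p = 0.000623, adjusted p = 0.612 with an estimated correlation). Replication-dependent histone genes rose in 19 of 52 cases and fell in 0 (20 and 0 alone), with Hist1h4m at 7.03 ± 0.361 against 2.16 ± 0.678 FPKM (camera adjusted p = 6.94e-09, adjusted p = 0.565 with an estimated correlation). Oxidative phosphorylation rose in 11 of 50 genes and fell in 2 (5 and 1 alone, camera adjusted p = 0.000506, adjusted p = 0.565 with an estimated correlation), and for the oxidative phosphorylation, nuclear-encoded list the call ended with a GC content and length correction (0.268). None of 13 mitochondrially encoded genes passed in limma, alone or over all genes, at a list median of 0.23 that was 0 with quantile normalization (camera adjusted p = 0.0388, adjusted p = 0.687 with an estimated correlation, 0.94 with quantile normalization). In the polyadenylation list Cpsf6, which encodes the partner of the Nudt21 protein, rose from 21 ± 0.134 to 31.3 ± 1.14 FPKM (log2 0.55, limma adjusted p = 0.00264), and 6 of 25 rose and 3 fell (6 and 6 alone, median -0.03, mean -0.02, camera direction above other genes, adjusted p = 0.612). Among m6A genes 2 of 20 rose and 1 fell (1 and 0 alone, median -0.06, camera direction above other genes, adjusted p = 0.896).

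T cell genes and markers of other cells were both higher. Cd3g rose from 272 ± 11.1 to 402 ± 18.8 FPKM (log2 0.56, limma adjusted p = 0.00285) and Cd3d from 154 ± 9.26 to 217 ± 7.01 FPKM (log2 0.5). In the T cell lineage genes 9 of 24 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.000341, adjusted p = 0.565 with an estimated correlation), at a median of 0.13 that quantile normalization put at 0.03 with no call (0.493). T cell activation genes rose in 9 of 41 cases and fell in 1, the same adjusted over the list alone, with Tnfrsf18 at 69.7 ± 0.0526 against 37.6 ± 1.07 FPKM (camera adjusted p = 5.24e-06, adjusted p = 0.565 with an estimated correlation). Effector and memory genes rose in 3 of 32 cases and fell in 1 (2 and 1 alone, camera adjusted p = 0.000548, adjusted p = 0.639 with an estimated correlation). The integrin gene Itgae rose, at 5.65 ± 1.01 against 0.764 ± 0.164 FPKM. Regulatory T cell genes rose in 4 of 16 cases, the same alone (camera adjusted p = 0.026, adjusted p = 0.657 with an estimated correlation), and for these regulatory T cell genes median-ratio scaling (0.107) and the GC content and length correction (0.0624) ended the call. Immediate-early genes rose in 11 of 27 cases and fell in 2, the same alone (camera adjusted p = 9.11e-05, adjusted p = 0.565 with an estimated correlation). Interferon-stimulated genes rose in 10 of 48 cases and fell in 1, the same alone (camera adjusted p = 9.11e-05, adjusted p = 0.639 with an estimated correlation). Cell cycle genes had a median of 0.2 with 2 of 55 higher and 1 lower (0 and 0 alone, camera adjusted p = 0.00459, adjusted p = 0.737 with an estimated correlation). With the marker score as a covariate the cell cycle and DNA replication median turned to -0.28 (0.0217). Naive genes fell in 7 of 29 cases and rose in 2, the same alone (camera adjusted p = 0.75).

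Beside these, B cell markers averaged 59.7 ± 15.9 FPKM in the Nudt21 knockout against 24.6 ± 5.26 in its wild type, CD8 T, NK and gamma-delta T cell markers 11.4 ± 0.192 against 3.79 ± 0.526, and myeloid markers 21.8 ± 3.42 against 8.66 ± 2.2 (n = 2 and 2). Passing members were 5 of 22 for B cells (1 adjusted over the list alone, camera adjusted p = 2.64e-06), 6 of 20 for CD8 T, NK and gamma-delta T cells (6 alone, 0.000161), 3 of 28 for myeloid cells (3 alone, 5.24e-06), 1 of 10 for erythroid cells (0 alone, 0.0689) and 1 of 4 for stroma (1 alone, 0.16), all higher. With an estimated correlation they were adjusted p = 0.612, 0.612, 0.612, 0.657 and 0.612. The gamma-delta receptor gene Trdc rose from 5.24 ± 0.641 to 34.8 ± 4.95 FPKM (log2 2.52, SE 0.43, limma adjusted p = 0.00316) and the protease gene Ctss from 96 ± 2.42 to 125 ± 2.85 FPKM (log2 0.38, limma adjusted p = 0.0055). Several lists that passed camera in this knockout did not pass fry. They were T cell activation (fry adjusted p = 0.0663), T cell lineage (0.0663), effector and memory (0.325) and regulatory T cell genes (0.282). Interferon-stimulated (0.282), cell cycle (0.584), oxidative phosphorylation (0.107) and mitochondrially encoded genes (0.528) did not either. Nor did B cell (0.159), CD8 T, NK and gamma-delta T cell (0.206) or myeloid cell markers (0.235).

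In limma 3475 genes (27.8%) passed between Nudt21 knockout and wild type, 1092 higher and 2383 lower, with 169 and 74 changed at least 2-fold. Median-ratio scaling gave 1693 higher and 1584 lower genes and TPM scaling 703 and 3415, so the balance of directions depends on scaling. With only the libraries of the 2 groups compared 4814 genes passed. The spread shared by all groups is thus likely too large for this comparison, the reverse of the Mettl3 knockout. The count was 5540 with library weights, 1617 without wild type 1, 1427 without wild type 2 and 1338 without knockout 2, and 68 of 108 passing genes of the naming rule lost their call when 1 library was left out.

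Both knockouts shared 1141 changed genes, against 1003 for independent lists (Fisher's exact test, odds ratio 1.3, p = 1.55e-09, over genes, which are not independent replicates). Of these, 743 moved the same way, 291 higher (184 for independent lists) and 452 lower (287), and 398 moved in opposite directions. Socs1, Cish, Bcl2 and Phlda3 were among those higher in both, and Adh1 among those lower in both. The knockouts share no control library. Without Mettl3 knockout 1 the shared count was 2053, without Nudt21 wild type 1 518, without Nudt21 wild type 2 463 and without Nudt21 knockout 2 472. It was 544 with library weights and 741 with no filter. Of the Mettl3 knockout's genes 3026 also changed with activation, 2240 the same way and 786 the opposite way (2834 for independent lists). Both comparisons were higher for 1258 genes (916 for independent lists) and both lower for 982 (527). The knockout was higher and activation lower for 458 (735), and the reverse held for 328 (657). The shared count was 962 with library weights, of which 728 moved the same way, and with the marker covariate 1478 moved the same way and 772 the opposite way. Without Mettl3 knockout 3 these were 1519 and 803. These comparisons share the 3 wild type libraries at 0 h. Groups simulated with no effect against those libraries gave 0 shared genes and a correlation of 0.28 over genes, against 0.25 observed, and a covariance of 0.01 against 0.142. With no effect simulated hardly any gene can pass in either comparison, so that 0 is no reference for the shared count. A correlation does not depend on the size of the noise, so the simulated 0.28 is no reference for the observed 0.25 either. Covariance does depend on it, and the observed value exceeded the simulated one by 0.131. Shared noise, simulated as independent between genes, thus gave only a small part of the observed covariance. How much of the shared count comes from the shared libraries was not measured, because they are too few to split. Of the Nudt21 knockout's genes 2780 changed with activation, 1422 the same way and 1358 the opposite way (2728 for independent lists), and without Nudt21 wild type 1, Nudt21 wild type 2 or Nudt21 knockout 2 that count was 1274, 1152 or 1081. With library weights it was 4446.

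The difference between the knockouts' changes was tested directly. Socs1 and Socs3 did not differ (log2 difference 0.01, SE 0.14, limma adjusted p = 0.966, and 0.34, SE 0.29, limma adjusted p = 0.432), which does not show that they changed alike. Cish rose more in the Mettl3 knockout (0.73, limma adjusted p = 0.00953, 0.0637 with library weights), as did Ube2l6 (2.55, limma adjusted p = 0.00266). Carns1 fell in the Nudt21 knockout and rose in the Mettl3 knockout, from 22.9 ± 3.38 to 46.5 ± 11.5 FPKM (log2 0.98, limma adjusted p = 0.00409, log2 difference 2.89, limma adjusted p = 0.000346). Armh2 (-2.89, limma adjusted p = 2.07e-05) and Gp5 (-2.82, limma adjusted p = 0.000131) rose in the Nudt21 knockout and did not pass in the Mettl3 knockout. Tsc2 moved lower in the Mettl3 knockout (-0.38, limma adjusted p = 0.00468). Interferon-stimulated genes were higher in the Mettl3 knockout's change for 14 of 48 (16 adjusted over the list alone, camera adjusted p = 0.0084, adjusted p = 0.962 with an estimated correlation). Ribosomal protein genes were lower in it for 8 of 76 (0 alone, camera adjusted p = 1.79e-12, adjusted p = 0.962 with an estimated correlation), a median difference of -0.29 that quantile normalization of the cytosolic ribosomal proteins put at -0.01 (0.972). Histone genes were lower for 10 of 52 (5 alone, camera adjusted p = 2.2e-07, adjusted p = 0.962 with an estimated correlation). Fry did not call interferon-stimulated (fry adjusted p = 0.207), ribosomal protein (0.207) or histone genes (0.153). Components of the mTOR pathway, at a median difference of 0.13, passed fry as higher (fry adjusted p = 0.0111) but not camera (camera adjusted p = 0.999). All genes had a median difference of 0.119. In limma 3164 genes differed, 2233 higher and 931 lower, and 1441 and 1457 with median-ratio scaling or 1072 and 1141 with quantile scaling, which moved the median of all genes from 0.119 to 0.018 and -0.003. Without Nudt21 wild type 1, Nudt21 wild type 2 or Nudt21 knockout 2 the count was 1826, 1792 or 1745, and with library weights it was 2035.

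The wild types of the sets differed as well. Socs3 stood at 156 ± 33.4 FPKM in the Nudt21 set against 64.1 ± 14.5 in the Mettl3 set (n = 2 and 3, log2 1.27, SE 0.2, limma adjusted p = 0.00277), Fosb at 81.2 ± 20.5 against 10 ± 4.47 FPKM (limma adjusted p = 0.00377, 0.061 with the replicate block) and Fos at 240 ± 12.6 against 139 ± 16.5 FPKM. Rps29 was lower, at 124 ± 1.86 against 234 ± 16.8 FPKM, with 39 of 76 ribosomal protein genes lower and none higher (53 and 0 adjusted over the list alone, camera adjusted p = 1.18e-23, adjusted p = 0.989 with an estimated correlation). All 13 mitochondrially encoded genes were lower, also alone (camera adjusted p = 3.06e-10, adjusted p = 0.989 with an estimated correlation). Erythroid and platelet markers averaged 29.8 ± 5.67 against 2.57 ± 0.508 FPKM, with 5 of 10 higher (5 alone, camera adjusted p = 0.262, adjusted p = 0.989 with an estimated correlation). The haemoglobin gene Hbb-bs stood at 86.1 ± 13.8 against 5.41 ± 2.06 FPKM (log2 3.8, limma adjusted p = 0.0334). That call was lost without Mettl3 wild type 1 (0.0752), 2 (0.0778) or 3 (0.0576) at 0 h or 1 (0.0515) or 2 (0.0504) at 48 h, without Nudt21 wild type 1 (0.173) or 2 (0.117), and with the replicate block (0.0792). Of 22 B cell markers 14 were higher (19 alone, camera adjusted p = 0.000115, adjusted p = 0.989 with an estimated correlation, fry adjusted p = 0.0914). In limma 3251 genes differed, 2337 higher and 914 lower in the Nudt21 set, with 1342 and 1409 under median-ratio scaling. These were 1030 and 1224 with quantile scaling and 240 and 414 with a GC content and length correction. Without Nudt21 wild type 1 the count was 643 and without Nudt21 wild type 2 it was 1455. By Xist and Ddx3y both Nudt21 wild types were male (Ddx3y 28.6 and 26 FPKM) and 2 of the 3 Mettl3 wild types female (Xist 52.2 and 46.7 FPKM). Sex is thus partly confounded with the set, and neither sex nor handling was separated from it.

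**Figure D4:**
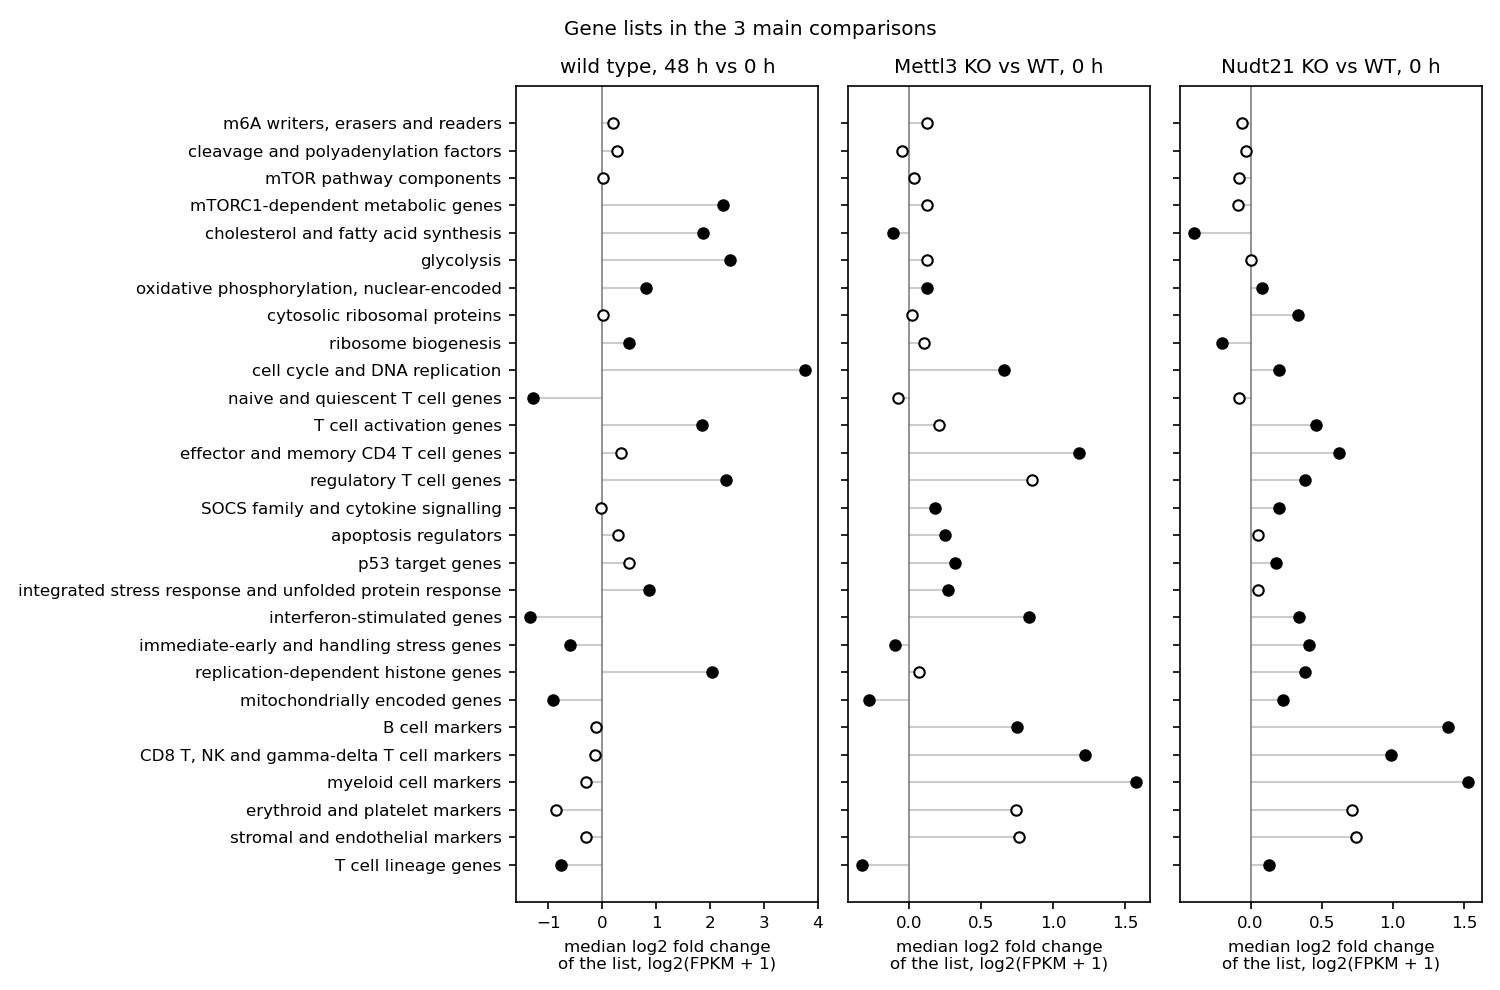
Median log2 fold change of the 28 gene lists in the 3 main comparisons, on log2(FPKM + 1), with a different axis in each panel. Filled points passed camera at its preset correlation and open points did not, and no list passed with an estimated correlation. Interferon-stimulated genes stand at -1.34 with activation and 0.83 in the Mettl3 knockout, and ribosomal proteins at 0.33 in the Nudt21 knockout (0.05 with quantile scaling).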

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

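The tests of marker transcripts, of interferon-stimulated genes and of library scaling were chosen after the results were seen, and the test of GC content and length before. Results were picked out for this part where the knockouts changed differently. In limma the change of 3164 genes differed between the Mettl3 and Nudt21 knockouts, and the count was 1826, 1792 or 1745 without Nudt21 wild type 1, Nudt21 wild type 2 or Nudt21 knockout 2. Ribosome biogenesis genes had a median difference of 0.31 (Mettl3 minus Nudt21 knockout), with 23 of 48 higher and 1 lower (28 and 1 adjusted over the list alone, camera adjusted p = 4e-05, adjusted p = 0.962 with an estimated correlation). The wild types already differed in this list, with 24 of 48 genes higher in the Nudt21 set and none lower. Its median there was 0.21 (camera adjusted p = 0.00151, adjusted p = 0.989 with an estimated correlation). Immediate-early genes had a median difference of -0.52, with 8 of 27 lower (9 alone, camera adjusted p = 9.87e-07, adjusted p = 0.454 with an estimated correlation). T cell lineage genes also had -0.52, with 18 of 24 lower (19 alone, camera adjusted p = 6.12e-12, adjusted p = 0.454 with an estimated correlation).

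Marker transcripts of other cells were higher in Mettl3 knockout library 3 and in both Nudt21 knockout libraries. In library 3, 100% of 70 B cell, myeloid and CD8 T or NK cell markers lay above the highest wild type library (25% by chance), with Igkc at 1238, S100a9 at 119 and Lyz2 at 91.8 FPKM. In library 1 the share was 25.7%, which argues against the loss of Mettl3 alone, and RNA of other cells in library 3 may be the source. In both Nudt21 knockout libraries 94.3% lay above both wild type libraries (16.7% by chance), with Igkc at 212 and 291 FPKM against 108 and 68.8. Members of the B cell, CD8 T or NK and myeloid lists moved together (estimated correlations of 0.897, 0.802 and 0.882). A single order of the libraries can therefore place most markers on top, and these shares do not measure chance. A lower share of CD4 T cells alone would lower the T cell lineage genes, of which 9 of 24 were higher and 1 lower (median 0.13). That explanation stays open, because under quantile normalization their median was 0.03 with no call, too little to decide it. Sorting for naive CD4 T cells would remove such cells, yet wild type libraries at 0 h all expressed 9 of 22 B cell, 5 of 28 myeloid and 7 of 20 CD8 T, NK and gamma-delta T cell markers at 1 FPKM or more, and a change within the T cells stays open.

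Interferon-stimulated genes were higher in both Mettl3 knockout libraries. With a score of other-cell markers as a covariate their median was 0.9, which argues against RNA of other cells as the whole source, although the score takes up most of what sets library 3 apart, so this value is nearly that of library 1. Xist and Ddx3y read as female in wild type libraries 1 and 2 and knockout library 1 and as male in wild type library 3 and knockout library 3 (Xist 52.2, 46.7, 39.4, 0.003 and 0.003 FPKM). With the replicate number as a block, which sets libraries of 1 sex against each other, the median was 0.73, which argues against sex. Loss of m6A, an infection or another exposure of these animals may each raise such genes, and nothing here separates them.

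Ribosomal protein genes were higher in the Nudt21 knockout, at a median of 0.33. Against the 20 nearest genes in GC content and length the median difference was 0.28 (interquartile range 0.15, 70 of 76 above), which argues against these biases as the whole source. The scaling stays open, because median-ratio scaling gave 0.43 and quantile normalization 0.05 for these cytosolic ribosomal proteins. With a correction for GC content and length the median was 0.22. The wild types of the sets differed by -0.31 in the same genes without any knockout (-0.52 with that correction), so RNA preparation may also move them and stays open.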

How the results depend on the processing

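Library weights, the marker covariate, the GC content and length correction, crossed numbers and list tests without Mettl3 knockout 3 were chosen after the results were seen. Total counts of genes kept within 1.5 times of the values in the report under other pseudocounts, a filter at a mean of 5 FPKM, the 3 scalings and the variance settings, while counts of higher and of lower genes moved by more with scaling, as the report gives. No call of a named gene turned direction in any setting. Among named genes a call was lost at least once for 0 of 35 with activation, 2 of 39 in the Mettl3 knockout, 4 of 34 in the Nudt21 knockout, 1 of 8 in the difference and 2 of 7 between wild types. These genes were printed mostly because they kept their call when a library was left out, so the low counts follow from that choice. Leaving out a Mettl3 knockout library also removes the spread between these 2 libraries from the shared estimate, so calls can be kept or gained for that reason. Of all passing genes of the naming rule, 6 of 121, 26 of 101, 68 of 108, 34 of 93 and 72 of 104 lost their call, in the same order. With a change of at least 2-fold required, counts were 3447 for activation, 340 for the Mettl3 knockout, 243 for the Nudt21 knockout, 432 for the difference, 53 for the wild types, 43 for both knockouts, and 187 and 103 for Mettl3 and Nudt21 knockout genes shared with activation, as fewer genes meet it. With fewer libraries (only the 2 groups compared) the Mettl3 knockout gave 809. No filter gave 741 for both knockouts. Library weights gave 1094 for the Mettl3 knockout, 5540 for the Nudt21 knockout, 2035 for the difference, 544 for both, and 962 and 4446 shared with activation. The GC content and length correction gave 654 between wild types. Median-ratio scaling put Mettl3 in Nudt21 wild types at 33 FPKM. The cause was not tested. No count test was run, because whole reads were not recoverable from FPKM, and depth therefore limits low genes to an unknown extent.

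Leaving out 1 library gave 9362 to 10128 genes for activation, 2576 to 4728 for the Mettl3 knockout, 1338 (without Nudt21 knockout 2) to 4741 (without Mettl3 knockout 3) for the Nudt21 knockout, 1745 to 4404 for the difference and 643 to 4249 between wild types. Both knockouts shared 463 to 2053, and those shared with activation were 2112 to 3890 for Mettl3 and 1081 to 3744 for Nudt21.

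The replicate block gave 728 genes between the wild types, where it compares the sets at number 1 only, and 729 for both knockouts, and changed the activation count to 9646. It changed no activation list call. For the knockouts the labels do not say what equal numbers mark, and 2 pairs each are too few to read it from the data. The correlations of equal numbers were 0.14 and 0.22 in the Mettl3 set, where they also match in sex by Xist, and -0.12 and -0.12 in the Nudt21 set. Counts with the block were 2728 and 2638. With Nudt21 numbers crossed in the block the wild types gave 1776 and the Nudt21 knockout 2952.

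Of the 28 lists 0 passed in each of the 5 comparisons with an estimated correlation, against 15, 15, 18, 7 and 7 with the preset one, and fry gave 7 for the Mettl3 and 8 for the Nudt21 knockout. The marker covariate gave 13 between wild types, and without Mettl3 knockout 3 the difference gave 15. Directions turned as follows, and the cause was not tested. Between wild types mTOR pathway components, at a median of 0.04, passed as higher in fry (adjusted p = 0.00771), against a camera direction below other genes. With quantile normalization cytosolic ribosomal proteins stood at 0.04 in the Mettl3 knockout and -0.01 in the difference, and mitochondrially encoded genes at 0 in the Nudt21 knockout. Without Mettl3 knockout 3, B cell markers stood at -0.15, myeloid cell markers at -0.14 and erythroid and platelet markers at -0.51. With the covariate they stood at -0.19, -0.11 and -0.42 in the Mettl3 knockout, myeloid cell markers at -0.26 in the Nudt21 knockout and -0.26 between wild types, and cell cycle and DNA replication at -0.28 in the Nudt21 knockout. These markers define the covariate, so their own values with it show little. The GC content and length correction put oxidative phosphorylation, nuclear-encoded, at -0.13 in the Mettl3 knockout.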

Other observations

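The test of exon density in the Mettl3 knockout itself was chosen after the result was seen, and those of the same trend elsewhere, of both motifs and of the splits before. Genes with 2 to 4 exons had the highest medians in the Mettl3 knockout. The 496 genes with 2 exons had a median log2 change of 0.25 and the 1537 with 3 to 4 exons 0.17, against 0.08 for 3052 genes with 5 to 8 exons, 0.01 for 3582 with 9 to 16 and -0.05 for 2209 with 17 or more. The 309 genes with 1 exon had 0.07. In the Nudt21 knockout the same groups, from 2 exons on, had medians of 0.05, 0.01, -0.05, -0.09 and -0.1, and 0.17 with 1 exon.

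A candidate explanation is that transcripts with few exons per kilobase, which carry more m6A in long exons, rise when the writer is lost. Partial Spearman correlations were taken over 11185 genes, given transcript length, GC content and mean level. With exons per kilobase the correlation was -0.175 in knockout library 1 and -0.086 in library 3. In the Nudt21 knockout it was of similar size (0.103, with a negative sign), while between the wild types it was -0.003 and with activation 0.07. Both knockouts thus showed the trend, which leaves the explanation open. Genes are not independent replicates, so no p-value is given. With DRACH motifs per kilobase, the m6A consensus, the lower partial correlation of the Mettl3 knockout libraries was 0.017, too near 0 to bear the explanation out. For UGUA motifs in the 3' UTR of 10976 genes, which the Nudt21 protein binds, the partial correlation nearer 0 of the Nudt21 knockout libraries was -0.017 (0.029 in the other). Motif number thus did not sort the changes beyond length, GC content and level. Without that adjustment the Spearman correlations were -0.088 and -0.187 in knockout libraries 1 and 2, and -0.404 between the wild types. Neither test measures m6A or polyadenylation sites.

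The 6 wild type libraries can be split 10 ways into 3 and 3, too few for a share under 0.05. In limma 1 split, the real one, gave 9822 genes, and the highest of the others gave 0 (127 at an unadjusted p under 0.05). The split with 127 kept a pair of equal replicate numbers together. Among the other splits that part every such pair the highest gave 64 at that unadjusted p.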
